A study of Mus musculus with 5 samples.

How the data were processed

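Gene expression was measured on 5 arrays, each hybridised with RNA from 1 pool of sorted mouse pancreatic islet cells. Per the labels, the cells were sorted by flow cytometry into Flattop-positive (3 arrays) and Flattop-negative (2 arrays) fractions. The donors were untreated C57BL/6 mice, 8 to 12 weeks old, with the heterozygous Flattop genotype FVR/+; each pool came from 4 to 6 mice, and sex had not been determined. Total RNA was extracted with the miRNeasy Micro kit and a DNase step, then amplified with Ovation PicoSL WTA reagents and labelled with biotin by the Encore module, per the labels.

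The deposited values are log2 signals per probe set. They were made by the authors with RMA in Affymetrix Expression Console 1.3.0.187, per the submitters' processing notes; RMA corrects background, normalises probes between arrays and summarises each probe set by median polish. The genome build is not given in the sources used here, so no coordinates are printed. The table holds 35556 probe sets on each array. Array medians lay between 4.74 and 4.98 and single values between 1.92 and 13.85, so probe sets had not been centred. No detection calls were used here. The number of arrays limits the precision of every value.

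Of the probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several and 12146 had no listed gene. Only those with 1 symbol were used. Of these, 21698 had a gene ID in the GRCm38.p6 gene table and 0 symbols changed. For the 999 genes with more than 1 probe set, the one with the highest mean signal was kept, which left 19938 genes. Ins1 and Ddx3y, which the naming rule also listed, were not analysed here.

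Groups were compared in limma 3.58.1 (R 4.3.3) by a linear model with group as the only term and moderated variances, two-sided, with Benjamini-Hochberg adjustment over all genes. Adjusted p-values are from this model unless another test is named. Genes at an unadjusted p under 0.05 and at least 1.5-fold were also counted. An exact one-sided permutation test of 3 against 2 arrays cannot give a p below 0.1. The limma p-values for single genes measure the spread between these pools. Replicate numbers come from the labels.

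There were 29 gene lists, holding 855 entries, of which 781 were matched to a gene tested. They covered islet cell types, acinar, duct, endothelial, immune, stellate, glial and red blood cells, and pathways. The 27 lists with at least 5 genes were tested with camera, which asks whether a list shifts relative to the other genes, at a preset correlation of 0.01 between genes, adjusted over lists. The test was repeated with the correlation estimated from the data, and with fry, which tests whether a list's own genes change, in 1 direction or either way, without setting them against other genes. At the preset correlation camera's p-values rest on the number of genes and do not measure the spread between pools. No list call held with an estimated correlation (0 of 27). Each list's median was also set against 10000 random lists of genes with similar mean signal, taken within 50 ranks on each side, an addition made after the data had been seen. Each gene was drawn separately, so these ranges leave out correlation between genes. The lists, the model and the naming rule were fixed before the data were examined.

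The genes named are the Flattop gene; the 10 highest and 10 lowest ranked, by unadjusted p among genes at least 1.5-fold apart without overlap where none passed the adjusted threshold, leaving out gene models, small RNAs and olfactory and vomeronasal receptors; up to 3 genes per list with the smallest p; and a fixed set of hormone, maturity, cyclin and sex-linked genes. Other genes named were chosen after their values had been seen.

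The model was tested on simulated data for this comparison over 19938 genes, with 200 changed genes in each of 10 runs. At an adjusted p of 0.05 it recovered 4% of genes changed by 1 log2 unit, 77.4% at 2 units and 93.8% at 3 units, with a mean of 7.7 false calls per run. The simulated genes varied independently, each with the same moderated spread in both groups. On the real arrays the median SD over genes was 0.202 between positive and 0.326 between negative arrays. These shares may thus be too high for the real data. Camera recovered 100% of lists shifted by 0.75 and called 0.459% of unshifted lists, in a simulation whose genes varied independently. Alternatives were the replicate number as a block, each array left out, dim genes left out, other normalisations, other probe set rules, another variance model, array weights, all probe sets and other thresholds. Cyclic loess and a block for the arrays with high Xist were added after the data had been seen. Tables were handled in pandas 2.3.3 and plots drawn in matplotlib 3.10.9.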

Results

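The series profiled pancreatic islet cells of mice heterozygous for a modified Flattop allele (FVR/+), sorted by whether they were positive or negative for Flattop. Flattop is the product of Cfap126, a gene of the ciliary apparatus and an effector of planar cell polarity. The title of the series names proliferative and mature β-cells, so the comparison asks how the sorted fractions differ in genes of β-cell maturity and proliferation. There were 3 Flattop-positive and 2 Flattop-negative arrays, all on a log2 scale. Across genes, the Flattop-negative pair correlated at r = 0.846, the lowest of all pairs of arrays, while Flattop-positive replicates 1 and 2 reached r = 0.984. The SD of the signal over genes was 1.83 to 1.93 on the positive arrays and 1.63 and 1.65 on the negative arrays.

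Cfap126 (probe set 10351517) had a mean log2 signal of 6.13 ± 0.10 (SD, n = 3) in the Flattop-positive arrays and 5.48 ± 0.05 (SD, n = 2) in the Flattop-negative arrays, without overlap. Its log2 difference was 0.64 ± 0.18 (SE), a 1.56-fold higher level that did not pass limma's test over all genes (adjusted p = 0.274). Genes of β-cell identity and of mitochondrial respiration lay higher in the Flattop-positive arrays as lists, with Slc2a2, the glucose transporter GLUT2, 2.79-fold higher and Ndufv1, a complex I subunit, 4.76-fold higher. Neither list call held with an estimated correlation (camera adjusted p = 0.219 and 0.270, unadjusted p = 0.00811 and 0.01997). That estimate was 0.009 for the β-cell list and 0.095 for the mitochondrial list, against the preset 0.01. A larger correlation was thus not what removed the β-cell call. With an estimated correlation camera uses the 3 residual degrees of freedom of the arrays, in place of the number of genes. Smarca1, a chromatin remodelling ATPase, lay 3.66-fold higher in the Flattop-negative arrays. Insulin 2 and glucagon transcripts were near the top of the scale in both fractions.

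Of 19938 genes, 0 passed an adjusted p of 0.05 in limma (smallest 0.198). At an unadjusted p under 0.05 there were 2760 genes, 13.8% of those tested, against 997 by chance. Of these, 2356 differed at least 1.5-fold, 1610 higher and 746 lower in the Flattop-positive arrays. That split was 1903 to 450 with arrays centred on their medians and 766 to 605 after cyclic loess. The groups did not overlap for 34.7% of genes, where chance gives 20%. Of these, 2735 were higher and 4187 lower in the Flattop-positive arrays, the opposite balance to that of the genes past the unadjusted threshold. Among 1027 olfactory receptor genes, which mark the floor, 8 were higher and 432 lower without overlap. The count of lower genes thus includes shifts at the floor of the arrays. Without Flattop-negative replicate 2, 434 genes passed the adjusted threshold, 360 higher and 74 lower, with the lone remaining array assumed to vary like the other group; without replicate 1, 0 passed, and the counts at the unadjusted p and 1.5-fold were 4722 and 4616. Without Flattop-positive replicates 1 and 2 in turn these counts were 1198 and 1511. The median log2 difference over all genes was -0.103 as deposited, -0.017 on repeated quantile normalisation, -0.033 with arrays centred and -0.012 after cyclic loess. As deposited it ran from -0.25 for genes with a mean signal under 4 to 0.55 for those over 9.

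**Figure D1:**
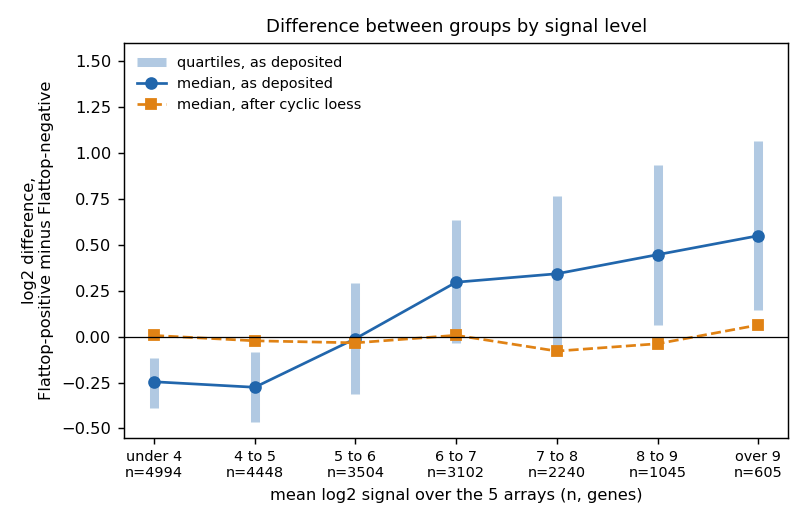
Log2 difference between Flattop-positive and Flattop-negative arrays (vertical axis) for genes binned by mean log2 signal over the 5 arrays (horizontal axis); points are medians and bars quartiles. The median runs from -0.25 in the dimmest bin to 0.55 in the brightest as deposited, and lies between -0.08 and 0.06 after cyclic loess.

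The β-cell identity and maturity list (31 genes) was higher in the Flattop-positive arrays, with a median log2 difference of 0.77 (camera adjusted p = 7.1e-09, and adjusted p = 0.219 with an estimated correlation). Random lists of similar signal had medians of 0.13 to 0.65 in their central 95%. Some markers of other cell types lay the other way, with medians of -0.36 for α-cells (uncalled), -0.46 for acinar, -0.44 for immune and -0.40 for stellate cells, while duct (-0.02) and δ, PP and ε (-0.15) lists were uncalled with means above 0. Without Flattop-negative replicate 2 those 4 medians were 0.02, -0.23, -0.09 and -0.17, all uncalled, and that of the β-cell list was 0.71. Of its genes, 27 lay higher and 4 lower. Adjusted over the list alone, 10 passed, all higher, against 0 over all genes tested. They were Slc2a2, Gipr, Ffar1, Glp1r and Ucn3, and, chosen after their values were seen, Pdx1, Nkx6-1, G6pc2, Trpm5 and Syt13. The incretin receptors Gipr and Glp1r rose by 1.65 ± 0.24 and 1.83 ± 0.34 log2 units (SE), and the fatty acid receptor Ffar1 by 1.72 ± 0.26, each adjusted over the list alone. Slc2a2 stood at 9.17 ± 0.11 (SD, n = 3) against 7.69 ± 0.22 (SD, n = 2), and Ucn3, a peptide of mature β-cells, rose by 1.21 ± 0.33 log2 units (SE) over the list alone. The Ucn3 difference was 0.71 without Flattop-negative replicate 2 and 1.71 without replicate 1, and that of G6pc2 0.80 and 1.76. The maturity factor Mafa was at 5.82 ± 0.26 against 4.98 ± 0.67 (adjusted p = 0.365), a difference of 0.36 without Flattop-negative replicate 1 and 1.31 without replicate 2.

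**Figure D2:**
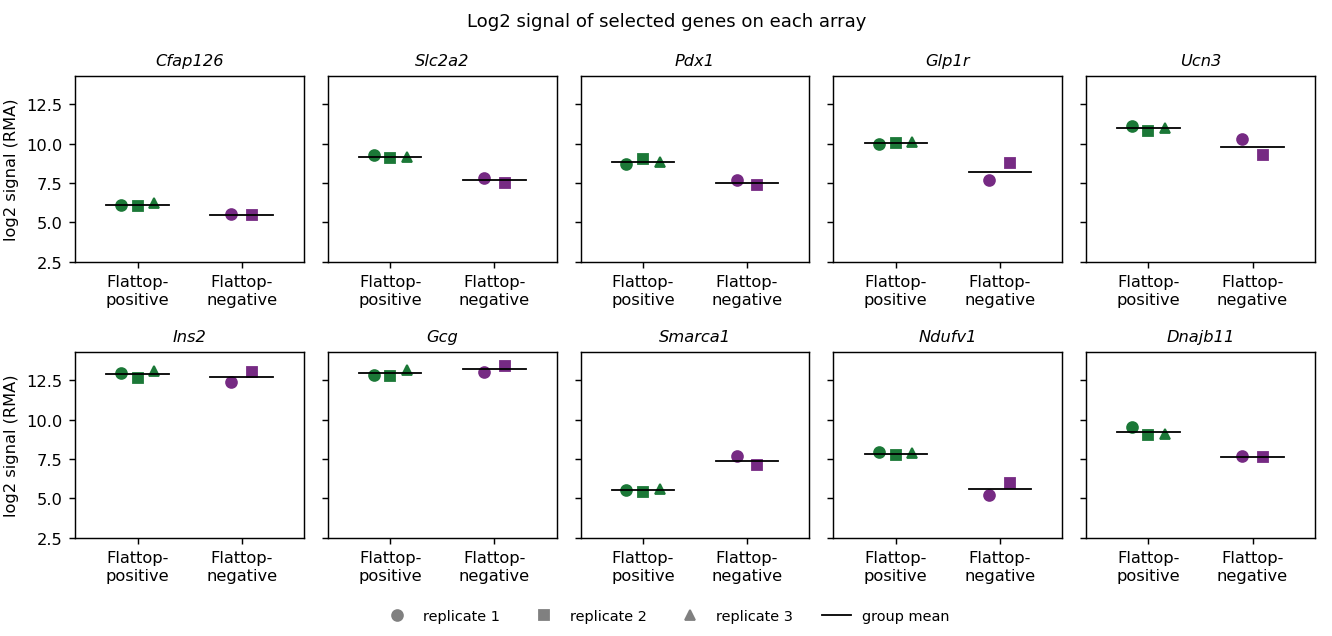
Log2 signal (vertical axis) of 10 genes on each array, by Flattop status (horizontal axis); symbols mark the replicate and lines the group mean. Slc2a2 and Ndufv1 are higher on all 3 Flattop-positive arrays and Smarca1 is higher on both Flattop-negative arrays, while Ins2 and Gcg overlap.

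The insulin granule and exocytosis list (24 genes) had a median of 0.25 (camera adjusted p = 0.00219, and adjusted p = 0.490 with an estimated correlation), and its sign turned after cyclic loess (-0.16) and on repeated quantile normalisation (-0.04). Its median lay inside the matched range of 0.11 to 0.70. Without Flattop-negative replicate 1 it was 0.10 and the call was lost (adjusted p = 0.124); without replicate 2 it was 0.71. The call was also lost with dim genes left out (adjusted p = 0.459). Rab3a, a GTPase of secretory vesicles, passed over the list alone, 2.59-fold higher. Ins2 stood at 12.89 ± 0.22 (SD, n = 3) against 12.71 ± 0.48 (SD, n = 2) and Gcg at 12.94 ± 0.20 against 13.23 ± 0.24. Both lay among the 19 genes within 1 log2 unit of the highest value on the arrays, which limits what their differences can show.

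The α-cell list (13 genes) had a median of -0.36 (camera adjusted p = 0.076), below the matched range of -0.22 to 0.43; 9 genes lay lower in the Flattop-positive arrays. It was called lower in 8 of 15 alternatives, among them cyclic loess (-0.36, adjusted p = 0.000687), repeated quantile normalisation (-0.46, adjusted p = 0.00488), without Flattop-positive replicate 3 (-0.43, adjusted p = 0.0362) and without Flattop-negative replicate 1 (-0.93, adjusted p = 0.0048), but without Flattop-negative replicate 2 the median was 0.02 (adjusted p = 0.922). Smarca1, the somatostatin receptor Sstr2 and the glutamate receptor subunit Gria3 fell by 1.87, 1.09 and 1.03 log2 units and passed adjusted over the list alone, Sstr2 from below the 95th percentile of olfactory receptor genes on 1 Flattop-positive array. The δ, PP and ε list (14 genes) had a median of -0.15 and a mean of 0.14, which differ in sign (camera adjusted p = 0.879). It was called lower without Flattop-negative replicate 1 (-0.77, adjusted p = 0.00981) and higher without replicate 2 (0.46, adjusted p = 0.0207). Sst stood at 8.08 in Flattop-negative replicate 1 and at 12.32 to 13.19 on the other arrays, and Ppy at 8.98 against 12.44 to 13.63. Without Flattop-negative replicate 2 both passed over all genes (4.44 and 3.86, adjusted p = 0.0412 and 0.0432), and without replicate 1 they had -0.67 and -0.78 and did not. Both also came within 1 log2 unit of the highest value on the arrays, which limits these sizes.

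The oxidative phosphorylation and mitochondria list (54 genes) had the largest median of the 27 lists tested, 0.92, and was higher in the Flattop-positive arrays (camera adjusted p = 4.9e-18, and adjusted p = 0.270 with an estimated correlation). The matched range was 0.24 to 0.65. This top rank was lost to glycolysis without Flattop-negative replicate 2 (0.71 against 1.61) and without Flattop-positive replicate 1 (0.87 against 0.93). It was lost to interferon genes without Flattop-positive replicate 3 (0.89 against 0.95). Of the genes of the mitochondrial list, 51 lay higher and 3 lower. Adjusted over the list alone, 22 rose and 1 fell, and 0 passed over all genes. Differences moved over 1.5 times without Flattop-negative replicate 2 for Ndufs3 (0.71), Cyc1 (0.78) and Cox5a (0.99), and without replicate 1 for Atp5b (0.82) and Atp5c1 (0.73), all named after their values were seen. Ndufv1 rose by 2.25 ± 0.29 log2 units (SE), Uqcrc1 of complex III by 1.97 ± 0.30 and the ATP synthase subunit Atp5o by 1.39 ± 0.20. The gene that fell was Ppargc1a, a coactivator of mitochondrial genes (-1.43 ± 0.40), named after its value was seen. List medians on the Flattop-negative arrays were 7.64 and 7.69, against 8.73 to 8.95.

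Glycolysis genes (12) had a median of 0.84 (camera adjusted p = 0.000183, and adjusted p = 0.591 with an estimated correlation); Pfkl, Tpi1 and Pgam1 rose over the list alone. Tpi1 and Pgam1 had 0.89 and 0.94 without Flattop-negative replicate 1, and Pfkl lay below the 95th percentile of olfactory receptor genes on both Flattop-negative arrays. The matched range was -0.07 to 0.72. Without Flattop-negative replicate 1 the median was 0.52 and the call was lost (adjusted p = 0.138); without replicate 2 it was 1.61. The ER stress and unfolded protein list (32 genes) had a median of 0.53 (camera adjusted p = 4.8e-07, and adjusted p = 0.490 with an estimated correlation), inside its matched range of 0.19 to 0.76, and the call was lost after cyclic loess (0.14). The chaperone genes Dnajb11, Hyou1, Creld2 and Pdia6 rose over that list alone, by 1.26 to 1.84 log2 units. Cholesterol and lipid synthesis genes (21) had a median of 0.60 (camera adjusted p = 0.000116, and adjusted p = 0.591 with an estimated correlation), with Fdps, Scd2, Lss and Acly rising over the list alone; this call too was lost after cyclic loess (0.21) and with dim genes left out (adjusted p = 0.0803), and the median was 0.32 without Flattop-negative replicate 2. Pdia6 and Acly were named after their values were seen.

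The 10 genes ranked highest, none past the adjusted threshold, included the mitochondrial ribosomal genes Mrpl34 and Mrps26, the proteasome subunits Psmb1 and Psmb3, the RNA polymerase II subunits Polr2f and Polr2j, and Ndufs7 of complex I, besides Naa38, Prrc1 and Tmem163. Their differences ran from 1.59 for Psmb1 to 1.99 for Psmb3, with an adjusted p of 0.198 each. The 10 ranked lowest were Smarca1 (-1.87), Khdc1a (-1.48), the recombination gene Rad54l, Pld1, Rasgrf2, Basp1, Igfbp4, Bmp8b, Slc6a12 and Zfp804a (-0.99), with adjusted p from 0.198 to 0.214. Khdc1a and Zfp804a lay below the 95th percentile of olfactory receptor genes on all 5 arrays, Igfbp4 on the 3 Flattop-positive arrays, Rad54l and Slc6a12 on 2 of them and Bmp8b on 1, so the sizes of their differences are uncertain.

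**Figure D3:**
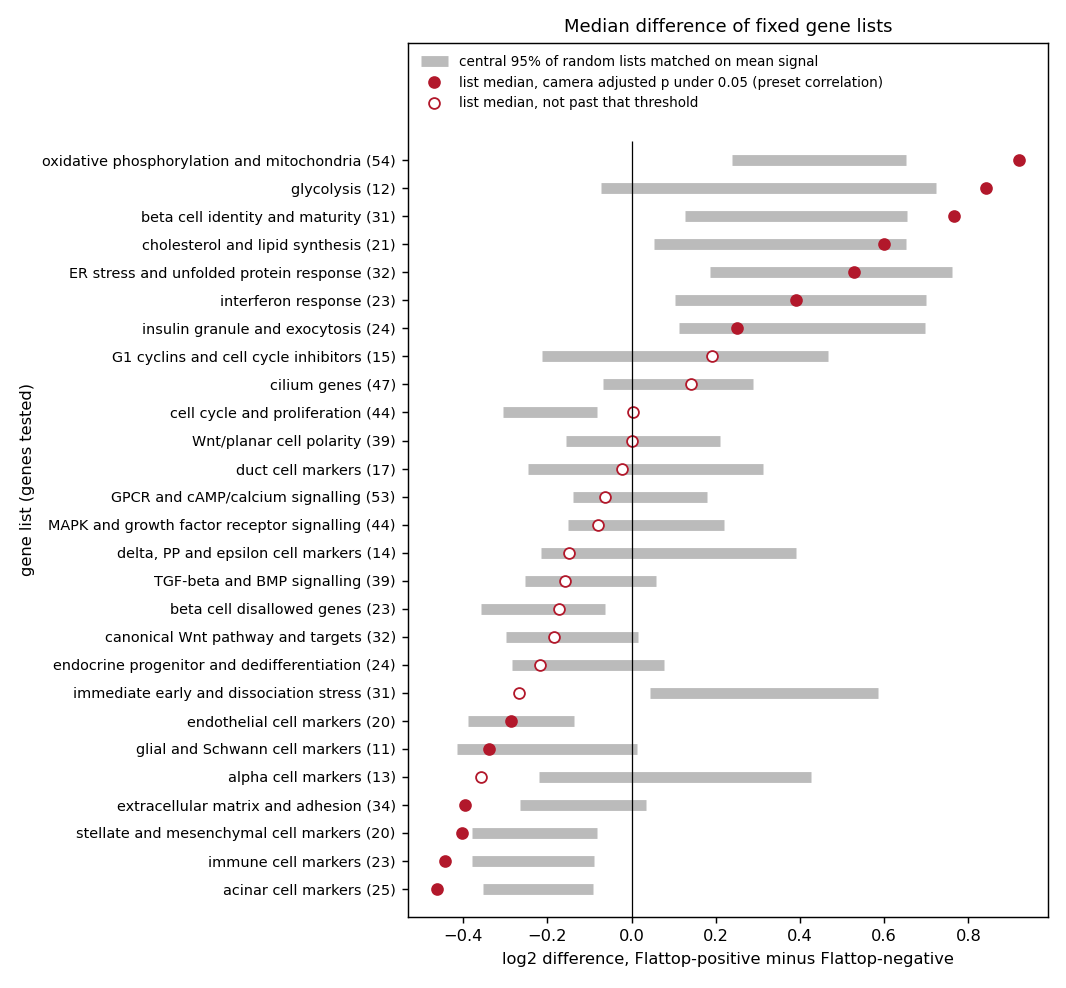
Median log2 difference of each gene list, Flattop-positive minus Flattop-negative (horizontal axis), by list with its number of genes (vertical axis). Filled points passed camera at the preset correlation, and grey bars give the central 95% of random lists of similar signal; mitochondrial genes (0.92), glycolysis (0.84), β-cell identity (0.77) and, uncalled, cell cycle genes (0.00) lie above their bars.

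Markers of 5 cell types outside the endocrine islet were lower in the Flattop-positive arrays, from low levels. Medians were -0.46 for acinar cells (25 genes; camera adjusted p = 0.00189, and adjusted p = 0.591 with an estimated correlation), -0.44 for immune cells (23; 0.00422, and adjusted p = 0.595 with an estimated correlation) and -0.40 for stellate and mesenchymal cells (20; 0.000705, and adjusted p = 0.595 with an estimated correlation). Endothelial markers had -0.29 (20; 0.0101, and adjusted p = 0.595 with an estimated correlation) and glial markers -0.34 (11; 0.0282, and adjusted p = 0.591 with an estimated correlation). Extracellular matrix and adhesion genes had -0.40 (34; 0.0294, and adjusted p = 0.626 with an estimated correlation). Adjusted over each list alone, 0 genes passed in these lists; Cela3b of acinar cells and C1qc of macrophages were among the genes with the smallest p in their lists, but each lay below the 95th percentile of olfactory receptor genes on 2 of the 3 Flattop-positive arrays, so no sizes are given. The acinar, immune, stellate and matrix medians lay below their matched ranges, and the endothelial and glial medians inside theirs. Without Flattop-negative replicate 2, 0 lists were called lower, and these medians were -0.23 (acinar), -0.09 (immune), -0.17 (stellate), -0.07 (endothelial), -0.19 (glial) and -0.03 (matrix). Without replicate 1 they were -0.77 for immune, -0.65 for stellate and -0.53 for endothelial markers. The glial call was also lost without Flattop-positive replicate 1 (-0.27, adjusted p = 0.0519), and the matrix call without Flattop-positive replicate 2 (-0.31, adjusted p = 0.0756) and with dim genes left out (0.14). Calls were lost as well with dim genes left out for acinar (-0.38) and immune markers (-0.32), after cyclic loess for immune (-0.22), endothelial (-0.05) and glial markers (-0.12), and on repeated quantile normalisation for endothelial (-0.04) and glial markers (-0.17). With a block for the arrays with high Xist, the glial (-0.31) and matrix (-0.27) calls were lost. On Flattop-negative replicate 2 the lysozyme gene Lyz2 was at 9.41 and Vim at 8.59, against at most 4.58 and 5.64 on the others. Duct markers had a median of -0.02 and a mean of 0.12 (camera adjusted p = 0.852), and the 3 red blood cell genes, too few to test, -0.10. The duct median was -0.29 without Flattop-negative replicate 1 and 0.10 without replicate 2.

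The cell cycle and proliferation list (44 genes) had a median of 0.00, with 22 genes higher and 22 lower (camera adjusted p = 0.601), and 0 genes at an unadjusted p under 0.05. The matched range was -0.31 to -0.08. The list was called lower without Flattop-positive replicate 3 (-0.38, adjusted p = 0.00652) and higher without Flattop-positive replicate 1 (0.26, adjusted p = 0.0144), so its direction hung on single arrays. Mki67, a marker of cycling cells, was at 4.15, 4.69 and 6.69 on the Flattop-positive arrays and at 4.45 and 5.12 on the Flattop-negative arrays. On replicate 1 of each group it lay below the 95th percentile of olfactory receptor genes. G1 cyclins and inhibitors (15) had 0.19 (camera adjusted p = 0.119); Men1, which encodes menin, passed over the list alone (1.22 ± 0.24). The G1 median was 0.34 without Flattop-negative replicate 1 and 0.75 without replicate 2, uncalled both times. The D cyclins Ccnd1 and Ccnd2 had differences of 0.87 ± 0.46 and 1.13 ± 0.49 (SE; adjusted p = 0.444 and 0.385). Without Flattop-negative replicate 1 they were 0.35 and 0.31, and without replicate 2 they were 1.38 and 1.94.

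Wnt/planar cell polarity genes (39) had a median of 0.00 (camera adjusted p = 0.521): Dvl3 had 1.33, Fzd3 0.74 and Wnt5b -0.98, and 0 passed over the list alone. Cilium genes (47) had 0.14 (0.0842), with Bbs9 at 1.03. Canonical Wnt genes (32) had -0.18 (0.0842), TGF-β and BMP genes (39) -0.16 (0.143), genes disallowed in β-cells (23) -0.17 (0.0842) and progenitor genes (24) -0.22 (0.134). The canonical Wnt, TGF-β and BMP, disallowed and progenitor lists were called lower without Flattop-positive replicate 3 (-0.27, -0.27, -0.40 and -0.30) and without Flattop-negative replicate 1 (-0.33, -0.40, -0.40 and -0.42), and the cilium list higher without the latter (0.34). Without Flattop-negative replicate 2 none of these 5 lists was called, with medians of -0.16, -0.07, -0.07 and 0.21 in the same order and 0.03 for cilium genes. Among the disallowed genes, Igfbp4 was lower over the list alone, from a level within the range of olfactory receptor genes on the Flattop-positive arrays. GPCR and cAMP/calcium genes (53) had a median of -0.06 and a mean of 0.14 (0.337), with Glp1r, Gipr, Ffar1 and Prkcb (named after its value was seen) higher and Sstr2 lower over the list alone; MAPK genes (44) had -0.08 and 0.05 (0.532).

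Several lists differed between arrays of a group. The immediate early and dissociation stress list (31 genes) had a median difference of -0.27 (camera adjusted p = 0.532), with list medians of 8.81 in Flattop-positive replicate 3 and 8.76 in Flattop-negative replicate 2, against 5.90 to 7.11 on the rest. It was called lower without Flattop-positive replicate 3 (-0.80) or Flattop-negative replicate 1 (-1.54) and higher without Flattop-negative replicate 2 (1.02). Interferon response genes (23) had a median difference of 0.39 (camera adjusted p = 0.0271, and adjusted p = 0.641 with an estimated correlation), with a sign that turned after cyclic loess (-0.06). Its call was lost without Flattop-positive replicate 1 (0.27), Flattop-positive replicate 2 (0.09) or Flattop-negative replicate 2 (-0.12), with dim genes left out (0.39), on repeated quantile normalisation (0.11), with arrays centred (0.46) and with the Xist block (0.13), and the median was 0.95 without Flattop-positive replicate 3 and 0.73 without Flattop-negative replicate 1. Flattop-positive replicate 3 and Flattop-negative replicate 2 had Xist at 7.81 and 8.62, against 3.58 to 4.36. The 4 sex-linked genes had a median difference of 0.12 and were too few to test; their mean was -0.22.

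**Figure D4:**
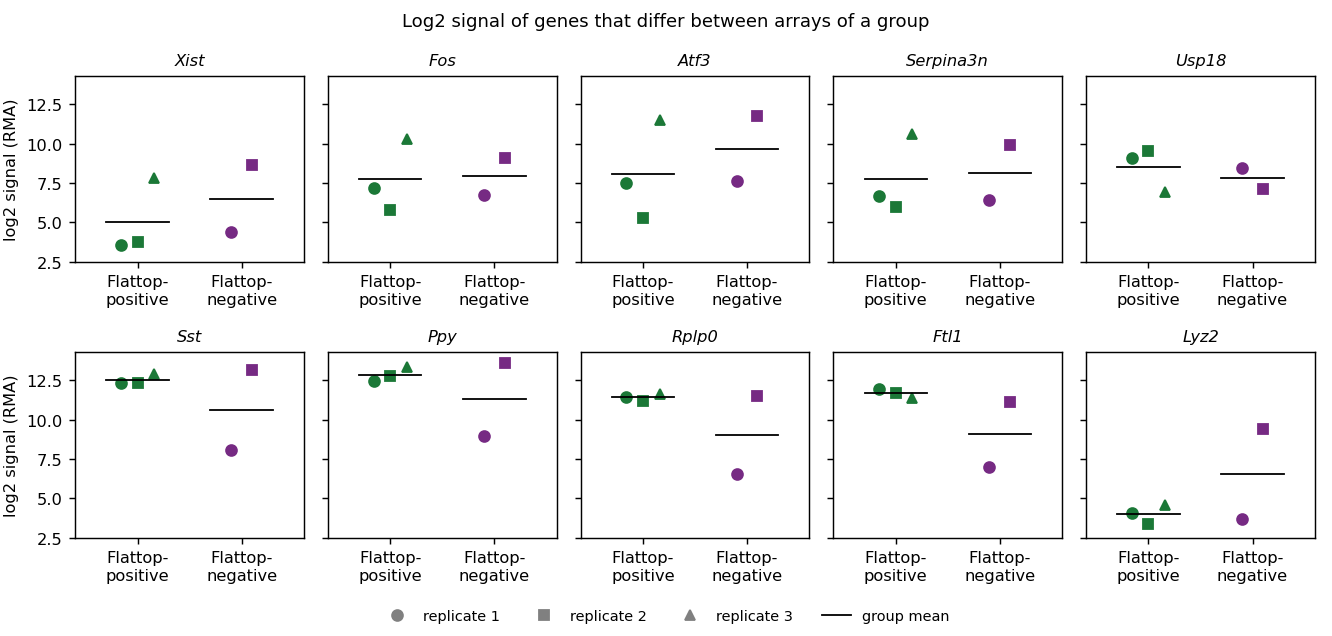
Log2 signal (vertical axis) of 10 genes on each array, by Flattop status (horizontal axis); symbols mark the replicate and lines the group mean. Xist, Fos, Atf3 and Serpina3n are high on Flattop-positive replicate 3 and Flattop-negative replicate 2, and Sst, Ppy, Rplp0 and Ftl1 are low on Flattop-negative replicate 1 alone.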

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

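Cyclic loess and the block for high Xist were chosen after the data had been seen. The count of genes past an adjusted p of 0.05 was 0 under every alternative except leaving out Flattop-negative replicate 2 (range over the leave-one-out fits 0 to 434); the smallest adjusted p in that fit was 0.0412. The 2356 genes at the unadjusted threshold became 1361 with dim genes left out and 3627 over all probe sets, where fewer or more features were tested, 1533 on repeated quantile normalisation, 1371 after cyclic loess and 786 at an unadjusted p of 0.01, and ranged from 1198 to 4722 with 1 array left out. Of 27 lists, 13 passed camera; 8 did after cyclic loess and 8 to 20 with 1 array left out. With an estimated correlation 0 passed (2 at an unadjusted p under 0.05), with fry 0 in direction (3 unadjusted; smallest adjusted p 0.0863) and 6 for change either way. With the Xist block 0 genes and 10 lists passed, and 2842 genes met the unadjusted threshold.

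The replicate number as a block gave 0 genes, 1775 at the unadjusted threshold and 20 lists, and turned the cell cycle list to -0.377. Replicate 3 exists only among the Flattop-positive arrays, so this block compares the same arrays as the fit without Flattop-positive replicate 3. That fit also had -0.377 for the cell cycle list. Both settings are counted in the tallies of alternatives, though they are not separate checks of direction. The deviations of same-numbered arrays from their group means correlated across genes at r = 0.182 (replicates 1) and -0.137 (replicates 2). With 2 Flattop-negative arrays, each r for replicate 2 is that for replicate 1 with its sign turned. These values thus cannot decide on a pairing. The labels name no shared source, so the numbers were not taken to pair the arrays.

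The insulin granule list turned to -0.158 after cyclic loess. With 1 array left out, list medians ranged from -0.377 to 0.261 (cell cycle), -0.771 to 0.457 (δ, PP and ε), -1.542 to 1.021 (immediate early) and -0.539 to -0.033 (matrix; the sign of its camera test turned), and log2 differences from -0.835 to 1.489 (Eif2s3y), -1.004 to 1.407 (Uty), -0.667 to 4.44 (Sst), -0.783 to 3.864 (Ppy) and -3.566 to 0.696 (Xist). Explanations for Sst and Ppy, and for the shared deviation of Flattop-positive replicate 3 and Flattop-negative replicate 2, are taken up below. Causes of the other ranges were not tested. A sign change was counted as a reversal only where 1 of the fits called a direction, for genes at an unadjusted p under 0.05; Eif2s3y and Uty did not pass the adjusted threshold in any fit (smallest adjusted p 0.0889 and 0.0656). Among lists without a call, those of α-cells gained one in 8 of 15 alternatives, immediate early genes in 7, canonical Wnt, TGF-β, disallowed and progenitor genes in 4 each, cell cycle genes in 3, and δ, PP and ε and cilium genes in 2 each. Of 402 list values under alternatives, 158 kept a call, 34 lost one, 38 gained one and 172 had none either way. Of 1654 gene values, 23 gained a call and 1631 had none either way, since no gene was called with all arrays. The β-cell identity and mitochondrial lists kept their camera call in all 15 alternatives fitted at the preset correlation, with medians of 0.53 to 0.90 and 0.55 to 1.04. Signal near the floor limits the dim lists: 2 of 20 endothelial markers in Flattop-negative replicate 1 exceeded the 95th percentile of olfactory receptor genes.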

Other observations

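Groups of housekeeping genes, most of them outside the lists and chosen after the ranked genes had been seen, also lay higher in the Flattop-positive arrays. Genes of mitochondrial ribosomal proteins (77) had a median log2 difference of 0.72, with 71 higher, though most of it came from 1 array (-0.272 in Flattop-negative replicate 1 and -1.021 in replicate 2, each against the Flattop-positive mean), and proteasome genes (50) had 0.87, with 46 higher. Complex I subunit genes (34) had 1.10, again more from replicate 2 (-1.322) than from replicate 1 (-0.615). Of these, 15 belong to the mitochondrial list and so partly restate it, and the other 19 had a median of 1.11. Cytosolic ribosomal protein genes (61) had 0.51, inside the 0.15 to 0.60 of random lists of similar signal.

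Single genes set the Flattop-negative arrays apart from each other. Pcsk1, a proinsulin convertase, was at 7.56 in replicate 2 and at 9.97 to 10.18 on the other arrays. The cilium genes Cep290 and Ift74 were at 7.96 and 8.31 in replicate 1 and at 3.85 and 4.40 in replicate 2. The Y-linked genes Eif2s3y and Uty were at 6.38 and 4.58 in replicate 2, and at no less than 7.78 and 5.90 elsewhere.

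Flattop-positive replicate 3 and Flattop-negative replicate 2 deviated from the rest of their groups in the same direction. The r was 0.225 across genes, which are not independent replicates (Spearman's rho 0.153). By construction the r with Flattop-negative replicate 1 was -0.225, so some pair of arrays had to give a positive r. Flattop-positive replicate 3 and Flattop-negative replicate 2 had higher Atf3 (11.51 and 11.74), Serpina3n (10.60 and 9.90) and Lbp (9.07 and 8.54) than the other 3 arrays. Their Usp18 was lower (6.94 and 7.13). Of the 10 splits of the arrays into 3 and 2, 1 (the real one) reached its 2356 genes at the unadjusted threshold, and the highest other gave 1735; the splits are too few for a share under 0.05. That other split set those 2 arrays against the rest and called 22 genes at an adjusted p of 0.05, where the real split called 0, which points to a structure of the samples other than Flattop status. The same 2 arrays had high levels of the sex-linked gene Xist (7.81 and 8.62, against 3.58 to 4.36 elsewhere). The Y-linked Uty was at 6.01 and 4.58 on them, low on the latter only. The sex of the pools had not been determined.

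Of the tests of explanations here, those of gene span and of the floor on group means were set before their results were seen; all others were chosen after. The higher mitochondrial and β-cell identity medians, 0.92 and 0.77, lay above the upper bounds of 0.652 and 0.654 for random lists of similar signal. These lists were drawn gene by gene, so their ranges leave out correlation between genes, estimated at 0.095 and 0.009. For the β-cell list, with its small estimate, the median argues against the trend with signal level as the whole cause. For the mitochondrial list the range may be too narrow to decide. Lists matched on signal and genomic span reached at most 0.761 in their central 95%, below the mitochondrial median. They were not matched on correlation either, so they cannot decide on short span as the whole cause. Genomic span is not transcript length, so a bias by transcript length was not tested. A wider loss of housekeeping transcripts from the Flattop-negative arrays cannot be told apart from a difference between the cells: mitochondrial ribosomal and proteasome genes differed by at least 0.72 between groups, and in Flattop-negative replicates 1 and 2 all 3 classes were below the Flattop-positive mean, but by unlike amounts (mitochondrial ribosomal -0.272 and -1.021, proteasome -0.793 and -1.022, cytosolic ribosomal -0.656 and -0.106). The cell make-up of the fractions was not tested as a cause of the β-cell identity difference.

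The non-islet marker lists were lower in the Flattop-positive arrays by a median of -0.403, and olfactory receptor genes, which mark the floor, by -0.272. That is a ratio of 0.675, above the bound of 0.5 set beforehand for a higher floor as the cause, so on group means the floor could account for most of the difference. The split by array was added after this result had been seen: in replicate 1 olfactory genes were raised by 0.303 and the markers by 0.118, while in replicate 2 they were raised by 0.19 and the markers by 0.591 (95% bootstrap interval 0.513 to 0.741). The interval is over 99 marker genes on 1 array, which are not independent replicates, so it does not measure spread between pools. By these values the floor alone leaves an excess in replicate 2 unexplained. Non-islet cells in that pool are a candidate source, with Lyz2 at 9.41 and the acinar genes Ctrb1 and Cpa1 at 6.86 and 6.53, but no test separated this from other causes.

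Sst and Ppy were low in Flattop-negative replicate 1 alone. Loss of some abundant transcripts that every cell uses could account for this: 16.4% of cytosolic ribosomal protein genes lay at least 2 log2 units below the lowest Flattop-positive array there, against 0% in replicate 2, with Rplp0 at 6.53 against 11.17 to 11.65 elsewhere. The loss was not general, as Gcg stood at 13.06 there against 12.81 to 13.39 elsewhere, and Actb at 11.35 against 12.34 to 12.86. Fewer δ and PP cells in that pool would, by the rule used, lower other bright markers by at least 2 log2 units too. Only 2 were measured, Rbp4 and Pyy, with gaps of -0.171 and -0.699 (median -0.435), both short of that size. With so few markers, fewer such cells and a loss of transcripts cannot be told apart.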
